A study of Homo sapiens with 6 samples.

How the data were processed

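Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in K562 cells, an established human leukaemia line. Per the labels, 3 modified K562 lines were used: a vector control, a line overexpressing wild-type SLFN11 and a line overexpressing SLFN11 with the E669Q substitution. Each line was given DMSO, or 1000 nM camptothecin (CPT) for 4 h, which makes 6 groups of 1 library. Groups were taken from the labels alone.

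The deposited files were 1 peak list per library. The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.2.6, SAMtools 1.8, Picard 2.9.2, MACS2 2.1.2 and the hg19 build, without stating the role or settings of each. Whether reads were shifted for the transposase, how duplicates were treated and how many reads were sequenced is not given in the sources used here. The authors gave each deposited peak a fold enrichment at its summit, which is a ratio over local background. They also gave each deposited peak a −log10 p-value and a −log10 q-value. The deposited score was the whole part of 10 times the −log10 q-value in every entry of the 6 lists. The lowest deposited −log10 q-value was 2.00 to 2.01 over the 6 lists, so the lists appear to end at a q-value of 0.01. Fold enrichments and p-values are the authors' own and were used to describe, rank or filter peaks within a list. They also served to recover depth, summit pileups and local backgrounds, which were compared between libraries. Peaks were listed per library, with no pooling of libraries.

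An interval can hold several summits, each with its own entry. Entries were counted for the number of peaks per library, and distinct intervals for everything else. Intervals of 2 lists were called shared when they overlapped by at least 1 bp (bedtools 2.31.1). An interval of the CPT list with no overlap in the DMSO list of its line is called gained, and the reverse lost. Regions over all 6 libraries were made by merging overlapping intervals. The overlap from chance was measured by placing the intervals of the shorter list at random 20 times. Coordinates are 1-based on hg19 as in the files.

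Relative depth was recovered from the deposited values. Assuming MACS2's formula with a pseudocount of 1, fold and −log10 p together give a whole summit pileup and a local background. Such a solution was found within 0.001 on the −log10 p scale for 98.7% to 99.3% of entries per list. The lowest background divided by the step between background values, each step being 1 fragment in a 10 kb window, gave the depth of a library relative to the shallowest. To compare libraries at equal depth, the deeper one was thinned by random binomial draws of its summit pileups (100 draws), and an interval counted as called when its p-value passed the lowest −log10 p of the shallower list. The scripts were tested on simulated data before use. In lists with a known part moved, 0 intervals were misassigned. Pileups were recovered for 100% of 500 simulated pairs per list. Over 20000 simulated sites thinning gave 0.982 times the true shallow count.

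With 1 library per group there is no replicate spread, and no test between single groups and no p-value across peaks was made. CPT and DMSO were compared over the 3 lines, paired by line, with an exact sign-flip test that cannot give a p under 0.25. Shares carry exact Clopper-Pearson 95% intervals, differences of shares Newcombe 95% intervals, and medians 95% intervals from binomial order statistics. All of these cover counting error only, and treat intervals as independent. Relations over the 6 libraries carry exact permutation p-values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

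The groups, comparisons, alternative thresholds, overlap rule and matched-length lists, in which each list holds its 5246 strongest intervals by −log10 p, were chosen before the data were examined. So was the rule for named regions: the 5 gained and the 5 lost intervals per line with the highest authors' fold. The attention to chromosome 19, to chromosomes 4, 5, 12 and 15, and to the gene-dense chromosomes was chosen after seeing the data. So were the 10 Mb bins, the 150 bp width limit, the counting of each summit and the thinning. The same holds for the ratio of shares with its log-normal 95% interval and for the pairing by line. Promoters, genes and the gene lists fixed beforehand were planned but not analysed here, because no hg19 annotation was used. The number of protein-coding genes per chromosome came from a RefSeq table of another build, without coordinates, and was divided by the largest peak end on that chromosome. By this measure the 6 most gene-dense chromosomes were 19, 17, 11, 16, 22 and 20.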

Results

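The series asked how SLFN11 affects chromatin under replication stress. SLFN11 is a Schlafen-family protein that binds stressed replication forks, and E669Q is a substitution in its ATPase domain. Camptothecin (CPT) traps topoisomerase I on DNA and stalls replication. ATAC-seq peak lists of 3 K562 lines (vector, wild-type SLFN11 and E669Q SLFN11) with DMSO, or with 1000 nM CPT for 4 h, were compared, 1 library each, so that no difference has a replicate check. Relative to the shallowest library, vector with DMSO, recovered depth was 1.09 in vector with CPT, 1.72 in wild-type SLFN11 with DMSO and 1.09 with CPT, and 1.33 in E669Q with DMSO and 2.22 with CPT. Median summit pileups were 9 to 12 fragments.

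The number of peaks moved in opposite directions in the SLFN11 lines after CPT. The wild-type SLFN11 library held 13603 peaks with DMSO and 6014 with CPT. The E669Q library held 9360 with DMSO and 14828 with CPT. The vector library changed least, from 5662 to 6280. Covered sequence was 3.80 and 1.55 Mb in the wild-type SLFN11 line, 2.59 and 3.86 Mb in the E669Q line, and 1.49 and 1.59 Mb in the vector line. Median interval width was 234 to 283 bp in the 6 libraries. Over the 6 libraries the number of intervals followed depth (Pearson r = 0.957, exact permutation p = 0.00556, adjusted 0.0167; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted 0.05; n = 6, 3 relations computed, Benjamini-Hochberg adjustment). Without the 2 libraries farthest from the median depth, r was 0.985.

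In the wild-type SLFN11 line many more intervals were lost than gained with CPT. Of 11651 DMSO intervals, 6937 had no counterpart after CPT and 4714 (40.5%, 95% interval 39.6 to 41.4) did. Of 5562 CPT intervals, 838 (15.1%) were gained, and 84.9% (84.0 to 85.9) overlapped the DMSO list. The lost intervals were weaker in the DMSO library than those found again, with a median fold of 5.70 against 7.10 and a median summit pileup of 9 against 15 fragments. Within the CPT library the gained intervals had a median fold of 4.91 and a pileup of 6, against 6.09 and 9 for the others. Thinned to the depth of the CPT library, the DMSO list held a mean of 8090 intervals (SD 40.1 over 100 draws), and the CPT over DMSO ratio of intervals went from 0.477 to 0.687.

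**Figure D1:**
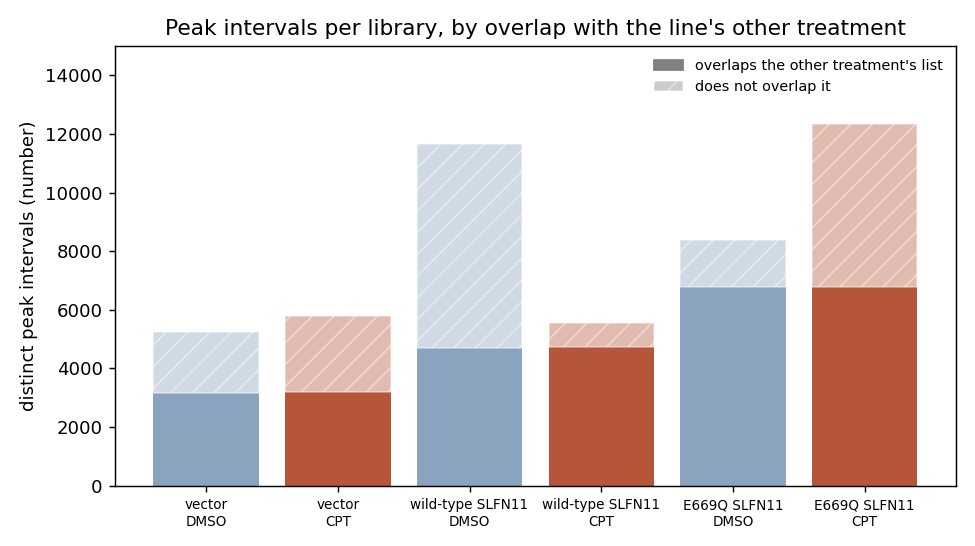
Number of distinct peak intervals per library (bars from 0), split by whether they overlapped the list of the other treatment in the same line. The wild-type SLFN11 list went from 11651 to 5562 intervals with CPT, and the E669Q list from 8365 to 12337.

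The E669Q and vector lines differed from this. In the E669Q line 5572 of 12337 CPT intervals were gained and 1590 of 8365 DMSO intervals lost, and 81.0% (80.1 to 81.8) of the DMSO list was found again. In the vector line 2621 of 5806 CPT intervals were gained and 2071 of 5246 DMSO intervals lost, and 60.5% (59.2 to 61.8) of the DMSO list was found again. Random placement gave 0.206% to 0.361% in the 3 lines. Thinned to the DMSO depth, the E669Q CPT list held a mean of 8700 intervals, close to the 8365 observed with DMSO. At matched length the shared part was 57.2% in the vector line, 61.4% in the wild-type SLFN11 line and 63.1% in the E669Q line.

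After CPT the wild-type SLFN11 list leaned towards chromosomes 19 and 17. Chromosome 19 held 4.51% of intervals with DMSO and 6.01% with CPT, a change of 1.49 percentage points (95% interval 0.778 to 2.24). Chromosome 17 went from 3.24% to 4.03% (0.783 points, 0.192 to 1.41). In the lists as deposited, the changes on chromosomes 16 (0.275 points, −0.312 to 0.898) and 22 (0.221, −0.138 to 0.619) had intervals that include 0. Chromosome 20 went from 1.73% to 1.44%. The 6 gene-dense chromosomes together went from 19.8% to 22.6%, a change of 2.82 points (1.52 to 4.15). In lists of matched length the chromosome 19 share went from 3.60% to 6.08%, a change of 2.48 points (1.66 to 3.30). There the change on chromosome 16 was 0.762 points, with an interval that excludes 0 (0.0595 to 1.47). That on chromosome 22 was 0.400 points (−0.0362 to 0.844). Chromosome 20 rose at matched length, from 1.18% to 1.43%, against a fall in the lists as deposited. Among gained intervals 8.47% (6.68 to 10.6) lay on chromosome 19, against 3.76% (3.33 to 4.24) of lost ones. The other lines went the same way by less. In the vector line these were 4.65% (3.88 to 5.53) and 3.48% (2.73 to 4.36), and in the E669Q line 5.38% (4.81 to 6.01) and 4.15% (3.22 to 5.25).

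Within chromosome 19 the change spread over several segments. At matched length, intervals between 40 and 50 Mb went from 30 with DMSO to 70 with CPT in the wild-type SLFN11 line, those between 0 and 10 Mb from 55 to 86, and those between 10 and 20 Mb from 39 to 70. Chromosome 11 between 60 and 70 Mb went from 24 to 51, and chromosome 17 between 40 and 50 Mb from 22 to 44. Chromosome 5 between 170 and 180 Mb fell from 45 to 26. These were the 10 Mb bins with the largest rises and the largest fall in this line.

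The chromosome 19 share was also larger with CPT in the vector line, from 2.25% to 2.89% (0.644 points, 0.0507 to 1.24; at matched length 0.572, −0.031 to 1.18). As a ratio in the deposited lists this was 1.29 times (1.02 to 1.62), against 1.33 times (1.16 to 1.52) in the wild-type SLFN11 line. At matched length by −log10 p the ratios were 1.25 (0.988 to 1.59) in the vector and 1.69 (1.42 to 2.01) in the wild-type SLFN11 line. Among intervals with −log10 q of at least 5 the change was 1.04 points in both lines (0.358 to 1.73 in the vector, 0.107 to 2.07 in the wild-type SLFN11 line). As a ratio this was 1.89 (1.23 to 2.897) in the vector and 1.25 (1.02 to 1.53) in the wild-type SLFN11 line. At fold of at least 5 the ratios were 1.45 (1.09 to 1.92) and 1.36 (1.17 to 1.59). The ratio was thus larger in the vector line at both thresholds, with overlapping intervals. It was larger in the wild-type SLFN11 line in the deposited and matched-length lists. In the E669Q line the chromosome 19 share was 5.56% with DMSO and 5.67% with CPT (0.115 points, −0.531 to 0.748). Its chromosome 17 share also rose with CPT, from 2.79% to 3.28% (0.497 points, 0.0171 to 0.965). At matched length that rise was 0.114 points (−0.464 to 0.693). In the vector list as deposited chromosome 17 changed by 0.187 points (−0.329 to 0.698). At matched length, the log2 share ratio of CPT over DMSO rose with gene density over 23 chromosomes in the wild-type SLFN11 line (rho = 0.687, and 0.642 without chromosome 19). In the vector line rho was 0.173 and in the E669Q line 0.267. In the lists as deposited rho was 0.236, 0.510 and 0.577 in the vector, wild-type SLFN11 and E669Q lines. The trends of both SLFN11 lines thus depended on list length, and as deposited that of E669Q was the larger. Matching kept 5246 of 11651 intervals of the wild-type SLFN11 list with DMSO, and 5246 of 5562 with CPT. Chromosomes are not independent replicates, and the difference between lines was not tested.

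**Figure D2:**
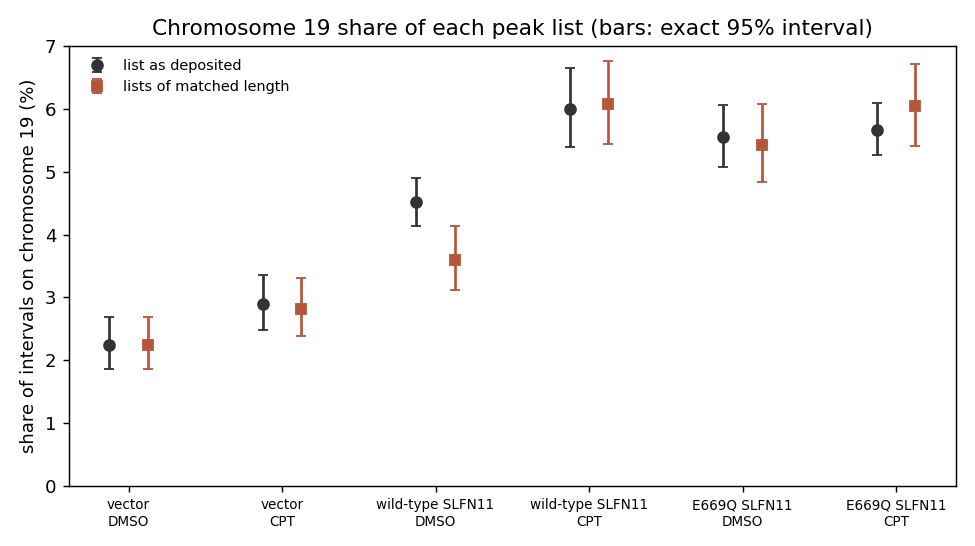
Share of peak intervals on chromosome 19 in each library (percent), in the lists as deposited and at matched length, with exact 95% intervals that cover counting error only. The vector libraries lie at 2.25% and 2.89% in the deposited lists and the wild-type SLFN11 library with CPT at 6.01%.

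**Figure D3:**
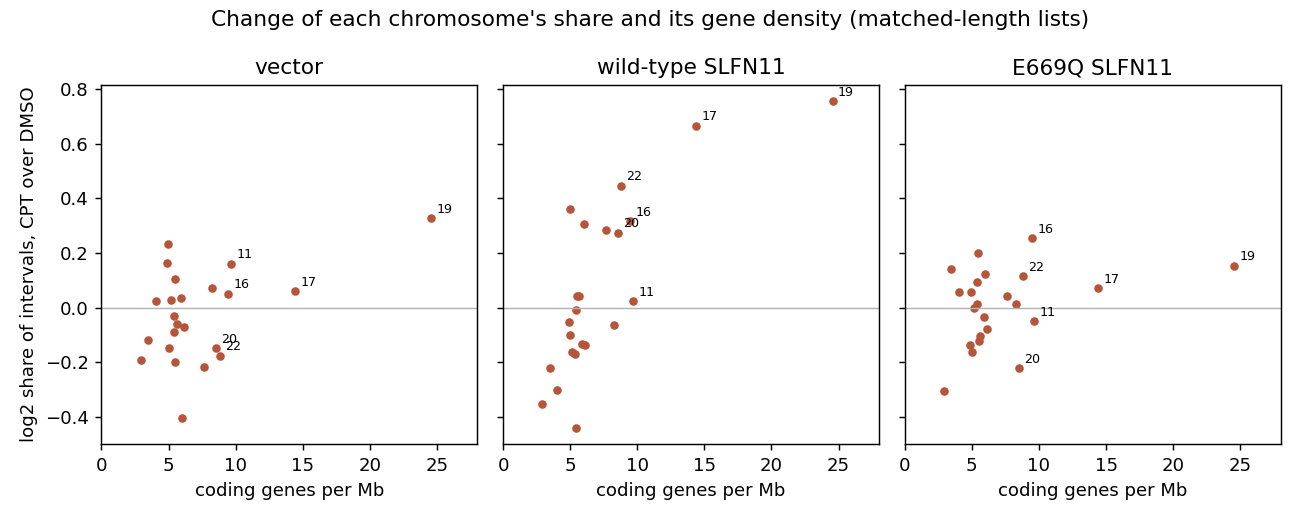
Each point is 1 of 23 chromosomes. The x axis gives protein-coding genes per Mb and the y axis the log2 ratio of its share of intervals, CPT over DMSO, in matched-length lists of each line. Spearman rho was 0.173 in the vector, 0.687 in the wild-type SLFN11 and 0.267 in the E669Q line. In the lists as deposited, not drawn here, it was 0.236, 0.510 and 0.577.

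The gained regions with the highest fold in the wild-type SLFN11 line were modest in size. They lay on chromosome 19 from 47551930 to 47552140 (fold 8.75), chromosome 17 from 80606149 to 80606425 (8.51), chromosome 12 from 50017123 to 50017384 (8.50) and from 114403939 to 114404120 (7.91), and chromosome 21 from 47621066 to 47621380 (7.70). Their summit pileups were 9 to 15 fragments. The region on chromosome 21 was in no other library, and the other 4 were also in the E669Q library with CPT. Those on chromosomes 19 and 12 were in the E669Q library with DMSO too, and that on chromosome 19 in vector with CPT. The lost regions with the highest fold were all narrow, 109 to 127 bp. They lay on chromosome 6 from 62284043 to 62284155 (48.1), chromosome 18 from 45379644 to 45379752 (43.4), chromosome 4 from 163342579 to 163342705 (32.5), chromosome 11 from 73221737 to 73221858 (27.2) and chromosome 9 from 44070666 to 44070789 (24.9).

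Several of these narrow regions recurred in other lines. Whether such narrow regions of high fold mark open chromatin was not tested, so they are not read here as changes in chromatin. In the E669Q line the gained region with the highest fold was on chromosome 6 from 62284043 to 62284154 (50.5). It was the same place as the top lost region of the wild-type SLFN11 line, and was called in the 2 deepest libraries alone. It was followed by chromosome 2 from 88124406 to 88124511 (39.9) and from 156120518 to 156120621 (28.6), chromosome 19 from 24184079 to 24184189 (24.8) and chromosome 9 from 42819063 to 42819187 (24.7). Its lost regions lay on chromosome 11 from 73221736 to 73221856 (26.3), chromosome 1 from 57684344 to 57684763 (10.9), chromosome 5 from 115420622 to 115420984 (10.2), chromosome 7 from 2353849 to 2354377 (9.06) and chromosome 6 from 26305450 to 26305758 (8.99).

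In the vector line the gained regions with the highest fold lay on chromosome 4 from 163342579 to 163342705 (32.7) and from 70296625 to 70296751 (17.2), chromosome 6 from 133593952 to 133594129 (17.02) and from 91078830 to 91079100 (10.96), and chromosome 1 from 120543915 to 120544068 (15.5). Its lost regions lay on chromosome 2 from 88124409 to 88124726 (41.3) and from 191402658 to 191402787 (18.3), chromosome 14 from 62217833 to 62218077 (10.6), chromosome 8 from 95565683 to 95565906 (10.5) and chromosome 12 from 98833922 to 98834109 (10.5). Each of these 10 regions was in at least 2 libraries of the SLFN11 lines.

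Among regions wider than 150 bp, the wild-type SLFN11 line lost chromosome 11 from 77597505 to 77597665 (fold 22.2), chromosome 2 from 74881227 to 74881553 (14.1) and from 169746688 to 169747143 (13.2), chromosome 8 from 18067475 to 18067864 (13.6) and chromosome 6 from 144384929 to 144385397 (12.8). The E669Q library with CPT had each of these 5, and both vector libraries had 3 of them.

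Both SLFN11 lines carried larger shares of chromosome 19 than the vector line, with and without CPT. With DMSO the share was 2.25% in the vector, 4.51% in the wild-type SLFN11 and 5.56% in the E669Q library. With CPT it was 2.89%, 6.01% and 5.67%. The differences from vector with DMSO were 2.27 points (1.70 to 2.80) for wild-type SLFN11 and 3.31 points (2.67 to 3.94) for E669Q. At matched length they were 1.35 points (0.710 to 2.01) and 3.18 points (2.46 to 3.93). With CPT they were 3.11 (2.36 to 3.88) and 2.78 points (2.17 to 3.36). The background of the 10 kb around shared intervals on chromosome 19 was also higher than in the vector line, relative to all shared intervals. On the log2 scale it was higher by 0.25 with DMSO and 0.54 with CPT in the wild-type SLFN11 line, and by 0.70 and 0.60 in the E669Q line. With DMSO the wild-type SLFN11 background was also higher on chromosomes 16 (0.25), 22 (0.23), 20 (0.20) and 17 (0.18), but hardly on chromosome 11 (0.008). In the E669Q line it was higher by 0.21 on chromosome 16, 0.22 on 22 and 0.24 on 17, and lower on 11 (−0.13).

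The comparison of wild-type SLFN11 with vector after CPT was the one at nearly equal depth. The lists held 5562 and 5806 intervals, and 57.5% (56.2 to 58.8) of the wild-type SLFN11 list overlapped the vector list. Of intervals in the wild-type SLFN11 list alone 9.05% (7.92 to 10.3) lay on chromosome 19, and of those in the vector list alone 1.81% (1.33 to 2.40). This split was not particular to wild-type SLFN11 after CPT. With DMSO it was 5.90% against 2.35% for wild-type SLFN11 and vector, and 8.15% against 2.23% for E669Q and vector. For E669Q and vector with CPT it was 7.23% against 0.877%. In the other comparisons the vector list was the shorter one. It overlapped the wild-type SLFN11 list by 84.6% and the E669Q list by 70.1% with DMSO, and the E669Q list by 84.3% with CPT. At matched length these shares were 60.8%, 56.2% and 58.2%.

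A set of 540 regions was found in all 4 libraries of the SLFN11 lines and in neither vector library. Of these, 15.4% (12.4 to 18.7) lay on chromosome 19 and 36.7% on the 6 gene-dense chromosomes. The mirrored sets were far smaller, with 21 regions in all vector and wild-type SLFN11 libraries alone and 27 in all vector and E669Q libraries alone. At matched length the 3 sets held 127, 109 and 58 regions, a much smaller excess.

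The E669Q lists differed from the wild-type SLFN11 lists on particular chromosomes at both treatments. Chromosome 4 held 4.69% of wild-type SLFN11 and 6.18% of E669Q intervals with DMSO, and 4.35% and 6.14% with CPT. Chromosome 15 held 1.81% and 2.51% with DMSO, and 1.46% and 2.78% with CPT. Chromosome 12 held 3.43% and 4.06%, then 3.33% and 4.33%. Chromosome 5 went the other way, with 6.20% and 5.30%, then 6.36% and 5.20%. The 95% interval of each of these 8 differences excluded 0. At matched length the interval for chromosome 12 with CPT included 0 (0.686 points, −0.0225 to 1.40). These chromosomes were picked from 23 after seeing the data. They were the only ones whose interval excluded 0 in the same direction at both treatments. The 8 exclusions thus follow in part from that choice, and carry no adjustment for the number of chromosomes.

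**Figure D4:**
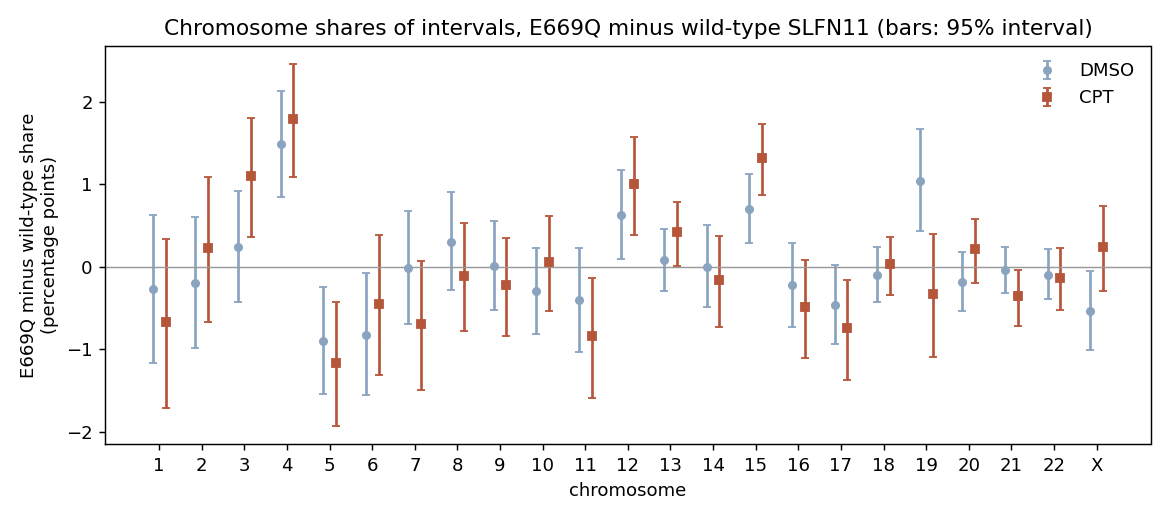
Difference in each chromosome's share of peak intervals, E669Q minus wild-type SLFN11, in percentage points at both treatments, with 95% intervals that cover counting error only. Chromosomes 4, 12 and 15 lie above 0 and chromosome 5 below 0 at both treatments.

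The 6 libraries did not group clearly by line or by treatment. The mean Jaccard index of covered bases was 0.331 for the 3 pairs of the same line, 0.301 for the 6 pairs of the same treatment and 0.310 for the 6 pairs sharing neither. At matched length the means were 0.345, 0.326 and 0.324. The most similar pair was wild-type SLFN11 with DMSO and E669Q with CPT (0.416; 0.386 at matched length), the deepest libraries of the series.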

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

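The tests here were chosen after the change in intervals was seen. Those by thinning and by finding intervals again were set before their own values were known; the calibration on the other lines and the relation over all 6 libraries were not. The number of intervals moved one way with CPT in the wild-type SLFN11 line (CPT over DMSO ratio 0.477) and the other way in the vector (1.11) and E669Q (1.47) lines. This drew attention because the lines differ in direction, and the difference was not tested, since each group is 1 library.

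Depth alone could give the number of intervals in the E669Q line: the DMSO list held 0.961 times the intervals of the CPT list thinned to its depth. This compares numbers and not which intervals were called. Of 8365 DMSO intervals, 1590 had no counterpart in the deeper CPT list. Depth and intervals also ranked together over the 6 libraries (rho = 0.943, exact permutation p = 0.0167, n = 6). In the wild-type SLFN11 line the CPT list held 0.687 times the thinned number, between the bounds set for depth as the cause (0.8) and against it (0.67), so depth could explain part of the fall and its full share cannot be told apart from other causes. Sites closed by CPT are a candidate explanation for the rest, since only 0.63 times the expected number of DMSO intervals was found again. The same ratio, also of DMSO intervals after CPT, was 0.731 in the vector and 0.841 in the E669Q line. Those values hold any effect of CPT, and come at other CPT over DMSO depth ratios (1.09 and 1.66, against 0.634). They therefore do not measure loss between untreated libraries. With the vector value also under the bound of 0.8, the test leaves closed sites open. A lower share of fragments in open chromatin, from the cells or from the preparation, was not tested.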

How the results depend on the processing

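With 1 library per group, replicates give no pairing. With CPT and DMSO paired within the 3 lines, an exact sign-flip test gave p = 1 for the log2 ratio of intervals and p = 0.25, the smallest it can give, for the chromosome 19 change (n = 3 lines, two-sided). Promoter windows were not run, since no hg19 annotation was used. Pairing by line, the ratio of shares, counting each summit, thinning, the gene-dense sets and the width limit were chosen after seeing the data. No direction of the interval ratio or of the chromosome 19 change reversed in any of the 3 lines under the alternatives run. Where not stated, the cause was not tested. At −log10 q of at least 5 the libraries held 2867 and 3351 (vector), 8810 and 2830 (wild-type SLFN11) and 5307 and 9715 peaks (E669Q; DMSO first), fewer by construction. Shared parts are listed as vector, wild-type SLFN11 and E669Q for CPT against DMSO, then wild-type SLFN11 and E669Q against vector with DMSO and with CPT. They were 57.2%, 61.4%, 63.1%, 60.8%, 56.2%, 55.7% and 58.2% at matched length by −log10 p. By fold they were 57.0%, 59.1%, 59.6%, 58.5%, 55.1%, 55.6% and 55.9%. With a reciprocal overlap of 50% they were 42.9%, 53.5%, 55.0%, 53.1%, 47.0%, 39.5% and 52.4%, lower by construction. Counting each summit gave 63.3%, 86.0%, 82.9%, 85.7%, 72.2%, 60.2% and 85.4%. At −log10 q of at least 5, CPT against DMSO gave 58.4% in the vector and 79.8% in the E669Q line, and the lines against vector gave 87.1% and 67.8% with DMSO and 54.1% and 83.2% with CPT. At fold of at least 5 the values that left their interval were 61.9% and 78.5% (vector and E669Q, CPT against DMSO) and 81.3% (E669Q against vector, CPT). The chromosome 19 change in the wild-type SLFN11 line was 2.48 points at matched length by −log10 p and 2.40 by fold, but 1.04 at −log10 q of at least 5, where it was also 1.04 in the vector and 0.493 in the E669Q line. On all 6 gene-dense chromosomes the change was 1.41 points in the vector, 2.82 in the wild-type SLFN11 and 0.818 in the E669Q line. At matched length by −log10 p it was 1.12, 5.47 and 0.972 points. Regions in the wild-type SLFN11 library with CPT alone numbered 329, and 116 at −log10 q of at least 5, 192 at fold of at least 5, and 718 and 713 at matched length by −log10 p and by fold. Such regions numbered 354 and 351 in the vector (DMSO first), 2226 in wild-type SLFN11 with DMSO, and 800 and 2589 in E669Q. At matched length by −log10 p these were 872, 743, 502, 628 and 666. Depth limits these results, since at median pileups of 9 to 12 fragments weak intervals can be missed in the shallower libraries.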

Other observations

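The tests of the chromosome 19 pattern and of the E669Q pattern were chosen after these patterns were seen. Those by thinning and gene density were set before their own values were known, and those of local background after. Of 17466 regions, 26 were in all 3 CPT libraries alone and 51 in all 3 DMSO libraries alone, while 570 were in both E669Q libraries alone, 143 in both wild-type SLFN11 libraries alone and 21 in both vector libraries alone. At matched length these sets held 70, 72, 216, 157 and 172 regions, so the gap between lines went with list length. The treatment sets ask for presence in 3 libraries and the line sets for fewer, so the sizes of the 2 kinds of set are not directly comparable. Regions found in 1 library numbered 6649 and those in all 6 numbered 2149. Chromosome 19 held 1.86% (1.33 to 2.53) of the regions in all 6, against 6.88% of those in 4. The regions in 4 libraries include the 540 regions of the SLFN11 lines alone, 83 of them on chromosome 19. Those in all 6 are also in the vector libraries, whose chromosome 19 shares are lower. The contrast thus in part repeats the difference between the SLFN11 lines and vector.

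Intervals of 150 bp or narrower made up 12.4% to 18.2% of the 6 lists. Among intervals with a fold of 15 or more they numbered 16 of 62 in the wild-type SLFN11 library with DMSO and 9 of 46 with CPT. They numbered 13 of 55 and 17 of 77 in the E669Q line, and 9 of 44 and 8 of 46 in the vector line (DMSO first). The narrow region on chromosome 6 from 62284043 was in the 2 deepest libraries alone, wild-type SLFN11 with DMSO and E669Q with CPT. Its −log10 q-values there were 926 and 1017.

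The larger chromosome 19 share of the wild-type SLFN11 line after CPT was not produced by thinning: the DMSO list at the CPT depth had 4.23% on chromosome 19, against 6.01% observed. At shared intervals on chromosome 19 the background of the surrounding 10 kb rose by 0.46 (log2, 95% interval 0.40 to 0.49). The summit there rose by 0.33, both relative to all shared intervals. The background rise was 1.39 times the summit rise, as a coverage shift over whole regions could give. This background also holds the fragments of the called sites and of sites nearby. It thus rises when called sites open, so opening of the called sites alone was not excluded. Background also rose by 0.33, 0.34, 0.26 and 0.21 on chromosomes 17, 22, 16 and 20, but by 0.01 (−0.04 to 0.05) on gene-dense chromosome 11, and on chromosome 19 it showed rises of 0.19 in the vector and 0.17 in the E669Q line. Opening over wide regions, more copies of early-replicating DNA in cells held in S phase, and a base-composition bias of a library could each give this, and were not separated here.

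The gaps between E669Q and wild-type SLFN11 on chromosomes 4, 12, 15 and 5 kept their sign in 8 of 8 cases after thinning. After a gene density trend was removed, 8 of 8 kept their sign and at least 50% of their size. These gaps were picked after seeing that they held at both treatments. Their persistence is therefore only weak evidence against depth and gene density as the whole cause. The local background at shared intervals moved with the share in 8 of 8 cases by over 0.1 (log2), for example by 0.42 and 0.33 on chromosome 12 and by 0.47 and 0.43 on chromosome 15 (DMSO and CPT). Against the vector line the E669Q background was also higher on chromosome 12 (0.30 and 0.31) and lower on chromosome 5 (−0.19 and −0.27), and the shift on chromosome 19 was larger (0.70 and 0.60), but wild-type SLFN11 with CPT also lay below vector on chromosome 5 (−0.14), and on chromosome 4 E669Q was above vector (0.25 and 0.16) and wild-type SLFN11 below (−0.09 and −0.22). The share gaps were uneven along chromosomes. With DMSO, chromosome 12 between 120 and 130 Mb held 0.66% of E669Q and 0.40% of wild-type SLFN11 intervals. Between 20 and 30 Mb it held 0.20% and 0.25%. Chromosome 5 held 0.13% and 0.26% between 10 and 20 Mb, but 0.54% and 0.50% between 140 and 150 Mb. These bins were picked after seeing the data, hold few intervals and were not tested. A candidate explanation is a difference in DNA copy number between the lines. ATAC-seq background alone does not separate it from a change in chromatin over wide stretches. Whether E669Q SLFN11 itself plays a part remains open, as 1 line carries it.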
